A study of Homo sapiens with 4 samples.

How the data were processed

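The series measured RNA from human CD34+ cells, the fraction of blood that holds hematopoietic stem and progenitor cells, isolated from umbilical cord blood and cryopreserved before use. The cells were incubated for 2 h at 4 °C in a serum-free medium with 10, 50 or 100 µM 16,16-dimethyl prostaglandin E2 (dmPGE2), a long-lived analog of prostaglandin E2, or with its DMSO vehicle. There were 4 arrays and 1 array per group. The labels do not say whether the 4 incubations came from the same donor or pool. Total RNA was isolated with a kit for small samples, amplified in 2 rounds, labelled with biotin and hybridized to Affymetrix HG-U133 Plus 2.0 arrays.

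The deposited values are on a log2 scale, 1 value per probe set and array. The submitters' processing notes name RMA, run in Affymetrix Expression Console, without versions. RMA corrects the background of each array, gives the arrays equal signal distributions and combines the probes of a probe set. Whether other arrays were normalized together with these 4 is not stated. Because the distributions were made equal, a shift of most genes one way would be removed before the values were written, and small differences are compressed near background. Log2 values were used as deposited, with no further scaling.

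Of 54675 probe sets, 62 control probe sets were set aside. Of the remaining 54613, the platform annotation, of 2016, gave 1 gene symbol for 41091, several symbols for 1801 and none for 11721. Of the 41091 probe sets, 41043 matched the RefSeq gene table by gene identifier, and 0 symbols changed. Each gene was represented by the probe set with the highest mean over the 4 arrays, which gave 19694 genes. Genes were kept when that mean lay in the upper 50% of non-control probe sets (mean log2 signal of at least 5.93), which left 12323 genes. Sex-linked marker genes, HLA genes and immunoglobulin and T-cell receptor genes, which can tell donors apart, were left out of counts and names. Positions are those of the GRCh38 build.

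With 1 array per group there is no replicate error, so each difference between a dose and the vehicle is a value with no test, and the number of arrays limits its precision. A difference of at least 1.5-fold was counted as a description of size. The same count was made for all 6 pairs of arrays, for each array in turn as the odd one out, and for all 12 orders of the 4 arrays. The only test run was a slope on the rank of dose (0, 1, 2 and 3), fitted with limma 3.58.1 (lmFit and eBayes with an intensity trend, two-sided) in R 4.3.3. Adjusted p follows Benjamini and Hochberg with a threshold of 0.05 over 12323 genes. The fit leaves 2 residual degrees of freedom and assumes that all arrays vary alike. On simulated data it recovered 12.0% of 50 genes given a 1.5-fold range over the doses, 98.0% at 2-fold and 100.0% at 4-fold and 8-fold. There were 6 false calls. The simulated slopes were straight lines, with noise taken from the 50 and 100 µM arrays, which differed least. The SD of log2 differences was 0.213 for that pair and 0.408 for vehicle and 10 µM. These shares can therefore overstate recovery on the real arrays.

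Gene lists, 27 in number, covered cAMP signaling and its targets, prostaglandin receptors, stress and metabolic pathways, stem cell identity and homing, and markers of other blood and stromal cells. Each list's median log2 difference was placed among 10000 random lists of the same size, matched on mean signal in 20 bins. A list stood apart when its median lay outside the central 95% of the random lists, and lists needed at least 5 kept genes. This is a description of these arrays and not a p-value. On the simulated data described for the slope, 2 of 100 random lists of 30 genes left unchanged stood apart. When shifted by 0.3 log2, 100 of 100 did. The simulated noise came from the arrays that differed least, and members of a real list can vary together. The rule may therefore perform less well on the real arrays than these shares show. Correlations between differences were set beside 100 simulations in which unchanged groups shared 1 vehicle array.

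The groups, the lists, the counts, the slope, the rule for named genes and most alternatives were chosen before the data were examined. The rule named, for each dose, the 10 genes with the largest difference in each direction whose other probe sets did not go the other way. It added up to 10 genes each way that were past 1.5-fold at all 3 doses, up to 10 each way in dose order, genes past the slope's threshold, CREM, NR4A1, NR4A2, NR4A3, FOS, CXCR4, PTGER2, PTGER4 and PTGS2, and list members past 1.5-fold at any dose. Genes of small RNAs, which these arrays measure only through longer transcripts, are given no value. Alternatives were equal array medians, cyclic loess scaling with 3 iterations, no filter, an upper 30% filter, the mean of a gene's probe sets, no cross-hybridizing probe sets, thresholds of 2-fold and 1.25-fold, other codings of dose, and each dose left out. Use of the 10 µM array as the reference, omission of that array from the dose order, and alternatives for the dose order within the cAMP list, were chosen after the data were seen. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.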

Results

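Expression was measured on 4 arrays, 1 each for CD34+ cord blood cells incubated for 2 h at 4 °C with vehicle or with dmPGE2 at 10, 50 or 100 µM. The stated purpose was to see whether more prostaglandin makes up for the weaker cell responses seen in the cold. Every value below comes from 1 array per group, without replicates. The 4 arrays had near-equal median log2 signals over all probe sets, 5.93 for vehicle, 5.91 at 10 µM, 5.92 at 50 µM and 5.94 at 100 µM. Hybridization spikes, control transcripts added to the labelled RNA, gave lower signal on all treated arrays than on the vehicle array. Several spike probe sets measure the same transcript, so they are not independent. The mean difference over 18 spike probe sets was -0.45 log2 at 10 µM (SD 0.148), -0.43 at 50 µM (SD 0.115) and -0.56 at 100 µM (SD 0.156). The log2 gap between 3-prime and 5-prime probe sets of ACTB was 4.26 for vehicle, 3.88 at 10 µM, 4.53 at 50 µM and 4.01 at 100 µM. For GAPDH it was 0.69, 0.24, 0.42 and 0.36 in the same order. Of 23 genes that mark differences between people, 16 were kept, and 0 of them differed by over 2-fold between any 2 arrays, against 420 of all 12323 kept genes (3.41%).

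Targets of cAMP and the transcription factor CREB were higher at 50 and 100 µM than with vehicle. Prostaglandin E2 raises cAMP through its receptors PTGER2 and PTGER4, so this list addresses the direct response to the drug. The median of its 31 kept genes was 0.25 log2 above vehicle at 10 µM, 0.46 at 50 µM and 0.48 at 100 µM. At 100 µM, 29 of the 31 lay above vehicle, 15 were past 1.5-fold higher and 0 past 1.5-fold lower. At 50 µM, 13 were past 1.5-fold higher and 0 lower, and at 10 µM, 6 were higher and 2 lower.

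The highest member of the cAMP list at 100 µM was GEM, a small GTPase, 3.92-fold above vehicle, with log2 differences of 1.0, 1.37 and 1.97 at 10, 50 and 100 µM. CREM, which encodes a CREB-related factor and the repressor ICER, was 0.71, 0.93 and 1.47 log2 above vehicle, 2.77-fold at 100 µM. The orphan nuclear receptor NR4A3 was at 0.69, 1.02 and 1.37 and NR4A2 at 0.87, 0.78 and 1.15. CREM and NR4A2 were read from probe sets that can cross-hybridize, but no other kept probe set of either gene lay below vehicle. The cAMP-degrading enzyme PDE4B was at 0.56, 1.27 and 1.35, PDE4D at 0.56, 0.63 and 0.95, and PDE4A at -0.16, 0.83 and 1.03, with another PDE4A probe set below vehicle at 50 µM. FOSL2, an AP-1 subunit, was at 0.28, 0.80 and 1.0, and the chemokine receptor CXCR4, which guides stem cells to marrow, at 0.24, 0.65 and 0.83. RGS2 was 0.78 higher at 100 µM and NFIL3 0.70. The phosphatase DUSP4 was at -0.67 log2 at 10 µM, where another of its probe sets lay above vehicle, and at 1.10 and 1.74 at 50 and 100 µM. The kinase SIK1 was at 0.69, 1.65 and 1.68 by a probe set that can cross-hybridize, but at 0.03 at 50 µM and 0.02 at 100 µM without such probe sets. ATF3 was at 0.52, 1.31 and 0.85, NR4A1 at 0.31, 0.56 and 0.65, and other probe sets of both genes disagreed: without cross-hybridizing probe sets, ATF3 stood at -0.14 and NR4A1 at 0.19 at 100 µM. Not all early genes were higher: FOS was at 0.28, -0.03 and 0.10, and JUNB at -0.88, -0.27 and -0.50.

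**Figure D1:**
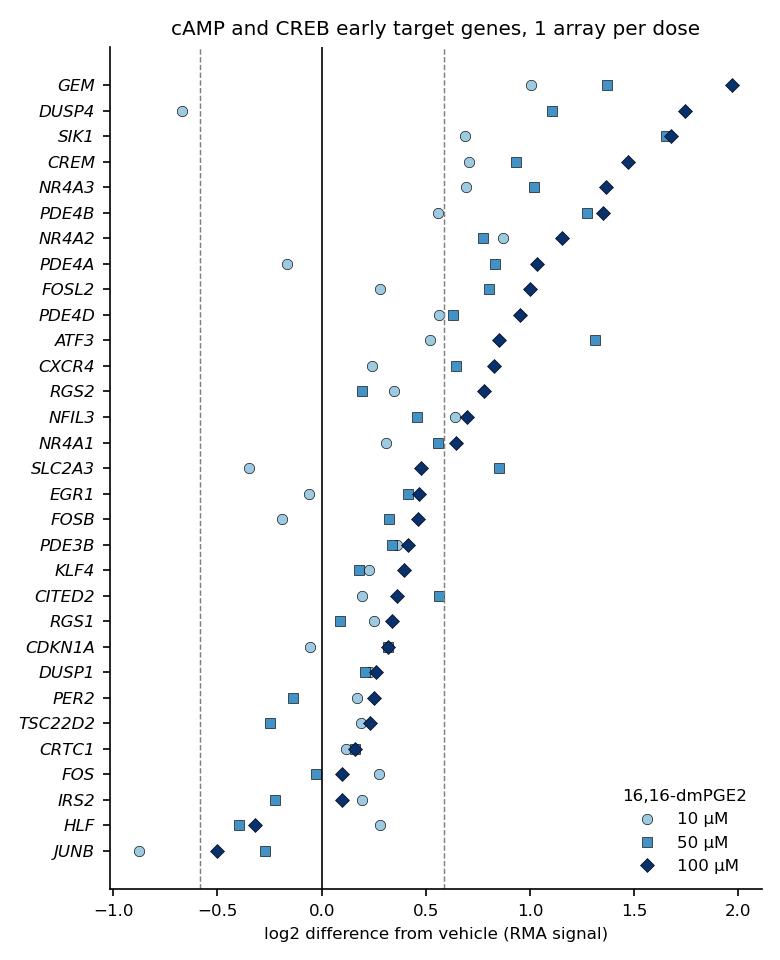
Log2 difference from vehicle (RMA signal, horizontal axis) of the 31 kept genes of the cAMP and CREB list, with 1 point per gene and dose and 1 array per dose; dashed lines mark 1.5-fold. At 100 µM 29 genes lie above zero, up to 1.97 for GEM, and JUNB is lowest at -0.50.

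The cAMP list's median at 50 µM and at 100 µM lay above all 10000 random lists, and that at 10 µM lay at the 84.3 percentile, within the random range. Between treated arrays, with the vehicle array not used, the median was 0.25 log2 higher at 50 than at 10 µM, 0.37 higher at 100 than at 10 µM, and 0.18 higher at 100 than at 50 µM, each above all 10000 random lists. Of the 31 genes, 9 (29.0%) were strictly ordered upward by dose, a share above all matched lists, against 394 of all 12323 genes (3.20%). The same 9 were also past 1.5-fold higher at 100 µM, and 111 of all 12323 genes met both conditions.

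At 10 µM, the 10 lowest genes lay farther from vehicle than the 10 highest, among genes whose probe sets did not disagree. C17orf99 was at -2.44 log2, with a signal of 5.73 below the filter's 5.93, and the ETS-family repressor ERF was 4.39-fold lower than vehicle (-2.13). The forkhead factor FOXO6 was at -2.03, the potassium channel gene KCNJ4 at -2.00, the polarity gene LLGL1 at -1.98, the kinase STK11 (LKB1) at -1.95, NFIC at -1.94, PBX2 at -1.83 and the stress ligand MICB at -1.82. Higher at 10 µM were the DNA damage kinase ATM (1.76), the TLR4 partner LY96 (1.5), VPS8 (1.41), the mTORC1 regulator RRAGB (1.37), SYNPO2 (1.33), NCLN (1.33), the transketolase-like gene TKTL1 (1.26), PLPBP (1.22), HINT3 (1.22) and SSX2IP (1.20). STK11 and NFIC were at -0.92 and -0.84 when all probe sets of the gene were averaged. Of the low genes, ERF, STK11 and NFIC lie on chromosome 19, C17orf99 and LLGL1 on chromosome 17 and KCNJ4 on chromosome 22. Genes of chromosomes 19, 17 and 22 lay low at 10 µM as a whole (percentiles 0, 0 and 0.03 of matched random lists). FOXO6, PBX2 and MICB lie elsewhere.

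In all, 1041 genes were past 1.5-fold higher at 10 µM and 728 lower (14.4% of kept genes), and 38 and 203 were past 2-fold. The split depends on scaling: with equal array medians it was 687 higher and 870 lower, and with cyclic loess, which shifted the median of all genes by -0.11 log2, 487 higher and 985 lower. The 10 µM array also differed by over 1.5-fold from the 50 µM array in 970 genes and from the 100 µM array in 614, while the 50 and 100 µM arrays differed in 155.

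Among the lists, 2 of 27 stood apart at 10 µM, both low, where 1.35 would be expected for lists of unrelated genes. Ribosomal protein genes had a median of -0.05 (21 kept genes, 0 past 1.5-fold higher and 1 lower), at the 0.185 percentile of random lists, with RPLP2 at -1.08. Without cross-hybridizing probe sets that median was 0.15, inside the random range. Immediate early genes, the first wave of transcription after a stimulus, had a median of 0.00 at the 1.29 percentile, with 2 of 40 past 1.5-fold higher and 6 lower. The lower members were IER3 (-0.97), JUNB (-0.88), MAFF (-0.79), JUN (-0.75), JUND (-0.73) and KLF2 (-0.62), while NR4A2 (0.87) and NR4A3 (0.69) were higher. JUNB, JUND and KLF2 lie on chromosome 19 and MAFF on chromosome 22, while IER3 and JUN lie elsewhere. Genes of these 2 chromosomes lay low at 10 µM as a whole (percentiles 0 and 0.03). The random lists were not matched on chromosome.

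**Figure D2:**
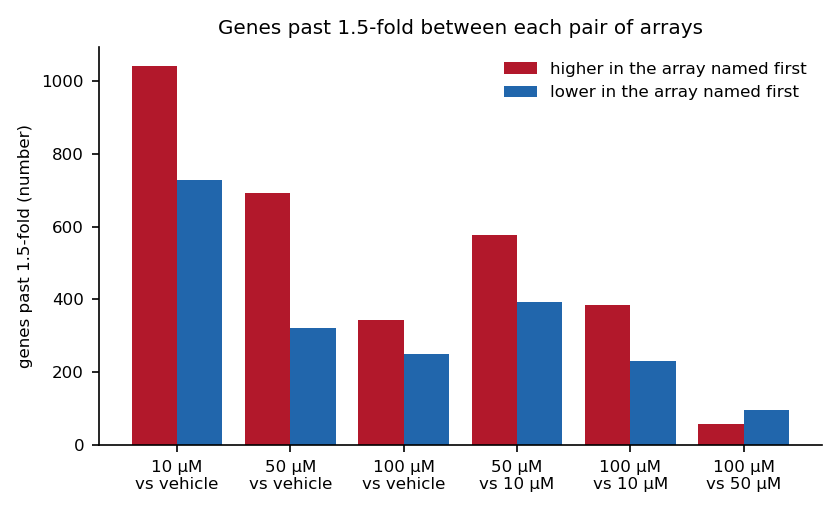
Number of kept genes past 1.5-fold between each of the 6 pairs of arrays (vertical axis, number of genes), higher in red and lower in blue in the array named first. The pair of 10 µM and vehicle has 1041 and 728 genes, and the pair of 100 and 50 µM 58 and 97; with cyclic loess the lower genes are the more numerous at 10 and 100 µM against vehicle.

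At 50 µM, TKTL1 was 2.61 log2 above vehicle and the cAMP-responsive noncoding RNA LINC00473 2.09. The vehicle signals of TKTL1 (4.96), LINC00473 (5.26), PIERCE2 (5.13), SYNPO2 (5.24), HSH2D (5.34), LY96 (5.68) and PLAT (5.88) lay below the filter's 5.93, so the size of their differences depends on values near background. Next were BABAM2-AS1 (2.04), the neutrophil chemokine CXCL5 (1.92), the peptidase ECEL1 (1.87), the Notch target HEY1 (1.79), PDLIM3 (1.73), SIK1 (1.65), the synaptic vesicle gene SV2C (1.59) and PIERCE2 (1.58). Among genes whose probe sets did not disagree, the lowest were C17orf99 (-2.10), FOXO6 (-1.95), the noncoding LOC101929305 (-1.73), KCNJ4 (-1.70), ERF (-1.63), the inhibin subunit INHBC (-1.61), the splicing factor SF3A2 (-1.60), PBX2 (-1.59), LLGL1 (-1.56) and PRRT3 (-1.46); ZNF777, with disagreeing probe sets, was at -1.75. Among the high genes TKTL1, BABAM2-AS1, CXCL5, HEY1, PDLIM3 and SIK1, and among the low genes FOXO6, KCNJ4, INHBC and PBX2, were read from probe sets that can cross-hybridize. BABAM2-AS1 and HEY1 were at 0.25 and 0.50 at 10 µM.

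Interferon response genes were also higher at 50 µM. Of 20 kept genes, 9 were past 1.5-fold higher and 0 lower, with a median of 0.44 log2 above all 10000 random lists, against 0.13 at 10 µM (70.2 percentile) and 0.02 at 100 µM (43.9 percentile). The antiviral GTPase MX1 was at 0.11, 1.16 and 0.17 log2 at 10, 50 and 100 µM, IFI44L at 0.42, 1.03 and -0.08, IFIT2 at 0.18, 0.77 and 0.00, and OASL at 0.72, 1.36 and 0.83. XAF1 was at 0.63, 1.13 and -0.22, with another probe set below vehicle at 10 and 50 µM, and IFIT3 at 0.15, 1.01 and -0.45, with another below vehicle at 10 µM. ISG20 (0.96) and MX2 (0.87) were also high at 50 µM and remained at 0.93 and 0.73 at 100 µM. Between the treated arrays, the list's median was -0.27 log2 at 100 relative to 50 µM, below all random lists, and 0.48 at 50 relative to 10 µM, above all of them. Some markers of other blood cells were also highest at 50 µM. The T and NK cell list had 3 of 14 genes past 1.5-fold higher at 50 µM and 0 lower, with a median of 0.10 (77.1 percentile). The cytotoxic granule gene GNLY was at -0.26, 0.72 and 0.01, the T and NK cell signaling chain CD247 at -0.11, 0.64 and -0.04, with another probe set below vehicle at 50 µM, and the monocyte gene FCN1 at 0.04, 0.66 and 0.18. The remaining T and NK gene past 1.5-fold, LCK, was not highest at 50 µM, with 0.75, 0.71 and 0.50. The myeloid list had 4 of 21 genes past 1.5-fold higher at 50 µM and 0 lower, with a median of 0.19 (96.5 percentile). They were FCN1, FCER1G (0.84), ELANE (0.82) and CD163 (0.63), of which only FCN1 and FCER1G were highest at 50 µM.

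Targets of NRF2, the regulator of antioxidant genes, formed the remaining list that stood apart at 50 µM. There were 3 such lists in 27, with 1.35 expected for lists of unrelated genes. Their median was 0.27 log2 (98.5 percentile), with 4 of 19 past 1.5-fold higher and 0 lower: the glutathione synthesis genes GCLC (0.81) and GCLM (0.62), heme oxygenase HMOX1 (0.72) and malic enzyme ME1 (0.65). Other probe sets of GCLC and GCLM went the other way, and the list's median was at the 97.1 percentile when probe sets were averaged. Over all genes, 692 were past 1.5-fold higher at 50 µM and 321 lower (8.22%), or 470 and 464 with equal array medians and 475 and 438 with cyclic loess, and 133 were past 2-fold.

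At 100 µM, the gene farthest above vehicle was again TKTL1 (3.08 log2), with a vehicle signal near background. LINC00473 (2.31), ECEL1 (2.12), CXCL5 (2.11), SV2C (2.09), the carbonic anhydrase CA2 (2.08), GEM (1.97), PDLIM3 (1.92), PIERCE2 (1.91) and the NF-kappaB adaptor MALT1 (1.81) followed. The lowest was LOC101929305, 5.61-fold lower (-2.49). The interferon-induced chemokine CXCL10 was at -2.44, although at -1.48 at 10 µM and 0.00 at 50 µM. The superoxide dismutase SOD2 was at -1.96 by its only probe set with 1 symbol. FOXO6 (-1.86), INHBC (-1.82), ERF (-1.71), C17orf99 (-1.70), LLGL1 (-1.51) and SF3A2 (-1.51) were low here as at 10 and 50 µM, whereas the erythroid regulator SOX6 was at -1.54 here, -1.59 at 10 µM and 0.04 at 50 µM.

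Fewer genes were past 1.5-fold at 100 µM than at 10 or 50 µM, 344 higher and 249 lower (4.81%), of which 114 were past 2-fold. With equal array medians the split was 322 and 255, and with cyclic loess 267 and 297.

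At 100 µM, 9 of 27 lists stood apart, 7 high and 2 low, with 1.35 expected for lists of unrelated genes. Members of a list can vary together and some lists share genes, so 1.35 is a low bar. Between treated arrays, which also differ in dose, 5 of 27 lists stood apart for 50 against 10 µM. For 100 against 10 µM and for 100 against 50 µM, 7 did in each pair. Immediate early genes had a median of 0.18 (98.8 percentile), with 10 of 40 past 1.5-fold higher and 1 lower. The polo-like kinase PLK2 was at 1.20 and BTG1 at 0.62, with the NR4A genes and FOSL2 as above, and the RNA-binding ZFP36L1 at -0.78. Unfolded protein and integrated stress response genes had a median of 0.20 (98.4 percentile), with 3 of 29 past 1.5-fold higher and 0 lower: ATF3, the amino acid transporter subunit SLC3A2 (0.73) and VEGFA (0.62). Sterol synthesis and uptake genes had a median of 0.23 (98.9 percentile), with 4 of 17 past 1.5-fold higher and 0 lower: STARD4 (0.91), SC5D (0.84), INSIG1 (0.60) and MYLIP (0.59), of which MYLIP had another probe set below vehicle. NRF2 targets had a median of 0.22 (99.2 percentile), with GCLM (0.82) the 1 of 19 past 1.5-fold.

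Markers of other cells stood apart at 100 µM too. Myeloid markers had a median of 0.18 (99.4 percentile), with 3 of 21 past 1.5-fold higher and 0 lower: the neutrophil elastase gene ELANE (0.88), CD14 (0.65) and FCER1G (0.61). Dendritic cell markers had a median of 0.21 (99.2 percentile), with 0 of 14 past 1.5-fold, and a mean of 0.12 within the random range (86.7 percentile). Stem and progenitor identity genes lay low, with a median of -0.04 (1.12 percentile) and with KIT (0.67) past 1.5-fold higher and LYL1 (-0.73) lower among 22, but their mean was 0.01 (11.9 percentile). The ribosomal median was 0.00 (0.84 percentile). Without cross-hybridizing probe sets, the immediate early (87.0 percentile), stress response (65.1), sterol (29.5), stem identity (9.51), ribosomal (55.1) and myeloid (97.49) lists were inside the random range, while the cAMP list was not.

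**Figure D3:**
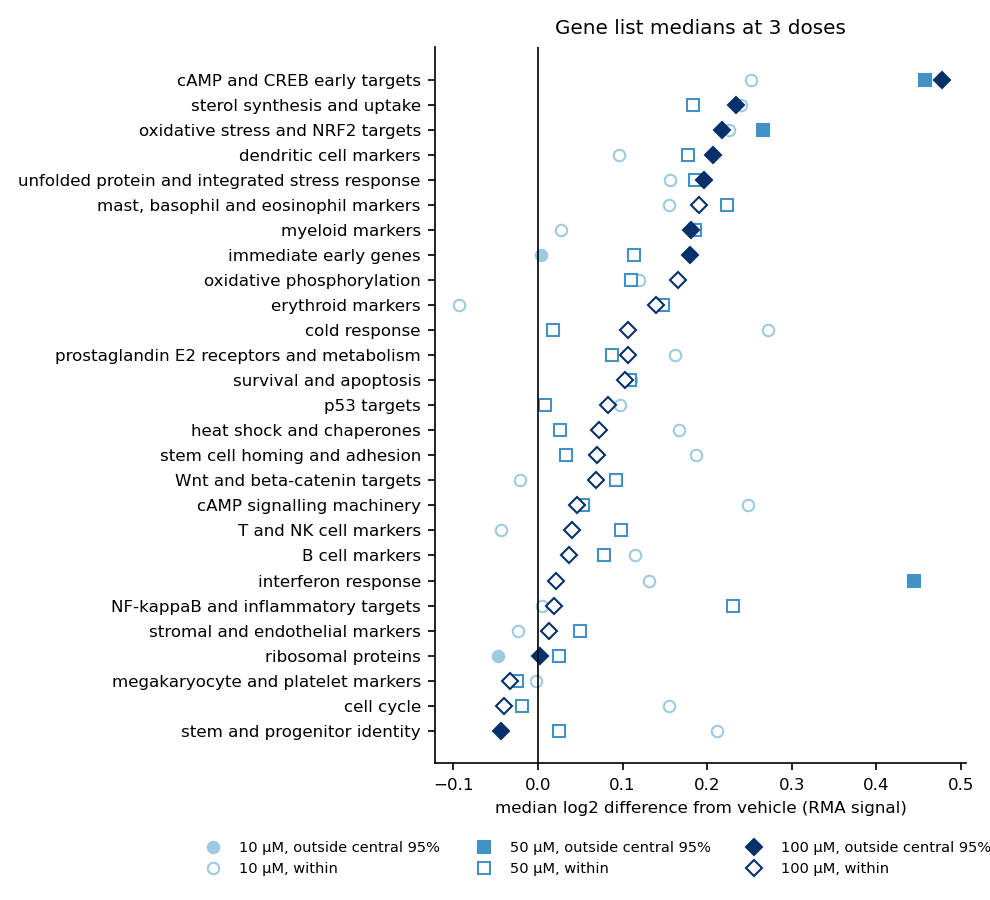
Median log2 difference from vehicle (RMA signal, horizontal axis) of 27 gene lists, with 1 point per list and dose; filled points lie outside the central 95% of matched random lists. The cAMP list lies at 0.46 and 0.48 at 50 and 100 µM, and the interferon list at 0.44 at 50 µM only.

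The lists for the prostaglandin pathway and for stem cell homing lay within the random range at all 3 doses. Prostaglandin E2 receptors and metabolism had medians of 0.16, 0.09 and 0.11 over 14 genes. The receptor PTGER2 was at -0.06, -0.53 and -0.54, PTGER4 at -0.60, -0.54 and -0.34, and the cyclooxygenase PTGS2 at 0.35, 0.20 and 0.44. The cAMP signaling machinery had medians of 0.25, 0.05 and 0.05 over 29 genes, with PDE8A at 0.67, 1.03 and 1.09 and RAPGEF3 at -0.63, -0.72 and -0.89. Stem cell homing and adhesion had medians of 0.19, 0.03 and 0.07 over 21 genes, with the sphingosine phosphate receptor S1PR1 at 0.70, 0.87 and 1.19 and PECAM1 at -0.69, -0.63 and -0.66, with another PECAM1 probe set above vehicle at 10 µM. Wnt and beta-catenin targets had medians of -0.02, 0.09 and 0.07 over 15 genes, with the Notch ligand JAG1 at 0.76, 0.60 and 0.75.

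The remaining lists also lay within the random range at all 3 doses. Survival and apoptosis genes had medians of 0.11, 0.11 and 0.10, with both BCL2L11 (0.40, 0.93 and 1.02), which promotes apoptosis, and BCL2A1 (0.37, 0.74 and 0.96), which opposes it, higher at 50 and 100 µM; at 10 µM another BCL2L11 probe set lay below vehicle. NF-kappaB targets had medians of 0.00, 0.23 and 0.02, with TNF at -1.15 and NFKB2 at 0.63 at 100 µM. Cold response genes had medians of 0.27, 0.02 and 0.11, heat shock genes 0.17, 0.03 and 0.07, p53 targets 0.10, 0.01 and 0.08, cell cycle genes 0.15, -0.02 and -0.04, and oxidative phosphorylation genes 0.12, 0.11 and 0.17. Among markers, erythroid genes had medians of -0.09, 0.15 and 0.14, megakaryocyte and platelet genes 0.00, -0.02 and -0.03, and mast, basophil and eosinophil genes 0.16, 0.22 and 0.19. B cell markers had medians of 0.11, 0.08 and 0.04, T and NK cell markers -0.04, 0.10 and 0.04, and stromal and endothelial markers -0.02, 0.05 and 0.01. Median and mean also had opposite signs at some dose for the Wnt, NF-kappaB, cold response, cell cycle, ribosomal, erythroid, megakaryocyte, B cell and T and NK cell lists.

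At all 3 doses, 120 genes were past 1.5-fold above vehicle and 143 below. Highest by their smallest difference were TKTL1 (at least 1.26), CA2 (1.14, 1.34 and 2.08), GEM, the transcription factor MAF (1.0, 1.42 and 1.57), SYNPO2 (1.33, 1.15 and 0.96), the plasminogen activator PLAT (0.96, 1.39 and 1.53), PIERCE2, MALT1, the BMP target ID1 (1.15, 0.91 and 1.11) and HSH2D (0.99, 0.91 and 0.97). Lowest were FOXO6, C17orf99, ERF, INHBC (-1.76, -1.61 and -1.82), LLGL1, SF3A2 (-1.79, -1.60 and -1.51), KCNJ4, ZNF777 (-2.15, -1.75 and -1.39), ERGIC1 (-1.59, -1.35 and -1.33) and HIVEP3 (-1.33, -1.42 and -1.47). Other probe sets of ZNF777 and ERGIC1 went the other way, as did 1 of MAF at 10 µM. The cAMP list gave 5 of the 120 and 0 of the 143.

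Taking each array in turn as the odd one out, the vehicle array gave 263 such genes, the 10 µM array 229, the 50 µM array 52 and the 100 µM array 10. With 4 arrays no share under 0.25 can be had, and the vehicle array is also the one with the highest spike signal. Across genes, which are not replicates, the differences at 10 and 50 µM had a Pearson correlation of 0.599, those at 10 and 100 µM 0.676, and those at 50 and 100 µM 0.771. Unchanged groups that share 1 vehicle array gave simulated values of 0.434, 0.522 and 0.658. The noise of the vehicle array could not be estimated and was set to the mean of the treated arrays. That variance was 0.0416, against 0.0794 for the 10 µM array. A noisier vehicle array would raise the simulated values, so the gap to the observed ones is no evidence of a shared response.

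Dose-ordered genes were mostly upward, but this was not particular to the order of dose. Every other order of the arrays that starts from vehicle also had more genes upward than downward. The split was 248 and 52 for vehicle, 100, 10 and 50 µM, and 300 and 280 for vehicle, 50, 100 and 10 µM. Of 155 genes whose signal went strictly one way over vehicle, 10, 50 and 100 µM and differed by 1.5-fold, 111 were upward and 44 downward. The 10 largest upward were TKTL1, LINC00473, ECEL1, CXCL5, SV2C, CA2, GEM, PDLIM3, PIERCE2 and MALT1. Downward at 100 µM were LOC101929305, HIVEP3 (-1.47), RPL27A (-1.47), the growth factor PDGFA (-1.33), the erythroid and megakaryocytic repressor GFI1B (-1.20), GPR146 (-1.07), TGFB1I1 (-1.07), CFAP73 (-1.04) and NEK6 (-1.0). CFAP73 stood at 0.07 without cross-hybridizing probe sets. RPL27A, PDGFA and NEK6 were also read from probe sets of that kind, as were MALT1, MAF, PLAT and ID1 and, among the genes named at 10 µM, ATM, RRAGB and SSX2IP. The cAMP list gave 9 of the 111 and 0 of the 44.

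The order of dose ranked 7 of the 12 possible orders of the arrays by number of genes. The highest, 758, came from vehicle, 100, 50 and 10 µM. With the 10 µM array left out, 367 genes were ordered over vehicle, 50 and 100 µM, 213 upward and 154 downward.

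The limma slope on dose rank passed the adjusted threshold for 2 of 12323 genes. TKTL1 (chromosome X, 154295795 to 154330350) rose by 1.06 log2 per dose step (SE 0.0939, adjusted p = 0.0162), from a log2 signal of 4.96 with vehicle to 8.05 at 100 µM. LOC101929305, a long noncoding RNA gene (chromosome 1, 201023949 to 201036676), fell by 0.838 per step (SE 0.0768, adjusted p = 0.0162), from 8.79 to 6.30. Over its alternatives the adjusted p of LOC101929305 ranged up to 0.729, and it did not pass without the 10 µM array (adjusted p = 0.0856) or without the 100 µM array (0.0823). LINC00473 and PIERCE2 (adjusted p = 0.0552 each), CXCL5 and SV2C (0.0806 each), ECEL1 (0.105), PDLIM3 (0.133) and GEM (0.181) did not pass. At an unadjusted p under 0.05 for this slope there were 370 genes (3.0%), fewer than the share of 0.05 that evenly spread p-values would give. With its probe sets averaged, TKTL1 had a slope of 0.70 (SE 0.0760, adjusted p = 0.112), and over the alternatives that could test it its adjusted p ranged up to 0.729. TKTL1 was called from a probe set that can cross-hybridize, and it was not tested without such probe sets or in the upper 30% by signal. The count was 0 for limma slopes on dose in µM (260 unadjusted), for any dose against vehicle (1367), without the intensity trend (324) and without the 10 µM array (949), and 28 without the 50 µM array.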

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

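The limits used to pick out both kinds of result here were chosen after the main differences were seen, and no explanation was tested for either.

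In all, 10 genes were past 1.5-fold from vehicle in opposite directions at different doses, and with 1 array per dose the differences between doses were not tested. The genes named here were chosen after their values were seen, except where the naming rule takes them. ATM was 1.76 log2 above vehicle at 10 µM, at -0.68 at 50 µM and at 0.62 at 100 µM, by a probe set that can cross-hybridize. DUSP4 was at -0.67, 1.10 and 1.74 log2, and another of its probe sets lay above vehicle at 10 µM. HINT3 was at 1.22 at 10 µM and -0.77 at 50 µM, where another of its probe sets lay above vehicle. The remaining genes were D2HGDH, DHRS2, GNL3L, PRKXP1, SEMA7A, SOCS3 and TRIM62. The cytokine signaling inhibitor SOCS3 was at -0.90, 0.63 and -0.19 and GNL3L at 1.32, -0.92 and 1.18. In all 10 genes the 10 and 50 µM arrays stood on opposite sides of vehicle.

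Among probe sets without a gene symbol, which no comparison used, 1 of the 4188 in the upper 50% by signal was at least 2-fold above vehicle at all 3 doses, and 12 were at least 2-fold below. The higher probe set was at 1.08, 2.42 and 2.62 log2 at 10, 50 and 100 µM.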

How the results depend on the processing

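The 10 µM array as reference, its omission from the dose order and the alternatives for the cAMP list's dose order were tested only after the results were seen; the other alternatives were planned. No paired analysis was possible because each group had 1 array, and for the same reason no replicate could be left out. The cAMP list stayed above the central 95% at 50 and 100 µM under all alternatives run, with medians from 0.23 to 0.51 at 50 µM and 0.37 to 0.68 at 100 µM, and inside it at 10 µM (0.10 to 0.26). Its members in strict dose order numbered 9, from 7 to 12 under 5 alternatives and 14 with averaged probe sets, where the cause was not tested. The interferon list stayed above that range at 50 µM. Correlations between doses, of 0.599 to 0.771, moved by less than 1.5 times, which says little about their stability. That ratio was the limit for counts, and the limit set for correlations was the SD of the correlations between doses. Of 117 list comparisons, 92 kept their side of the range, 24 returned inside it and 1 reversed, the ribosomal median at 100 µM relative to the 10 µM array (0.0482). Of 582 comparisons of named genes, 528 stayed within the spread between arrays, 52 moved further and 2 reversed without cross-hybridizing probe sets, ATF3 (-0.14) and CFAP73 (0.0670, both at 100 µM); the cause was not tested. Signal near background limits genes such as TKTL1 and LINC00473, whose vehicle signals of 4.96 and 5.26 lay below the filter's 5.93.

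Counts followed the threshold by construction. At 2-fold they were 241 genes at 10 µM, 133 at 50 µM, 114 at 100 µM, 29 at all 3 doses and 51 in dose order. At the smaller threshold they were 5120, 3606, 2422, 1316 and 342. The mean of a gene's probe sets gave 1163 genes at 10 µM and 170 at all 3 doses. The upper 30% filter, with fewer genes tested, gave 99 in dose order. Leaving out the 100 µM array gave 480 genes past 1.5-fold the same way at the other doses, and leaving out the 10 µM array gave 367 in dose order. For the limma slope, with 2 calls, equal array medians gave 9, the upper 30% filter 5, averaged probe sets 1, no cross-hybridizing probe sets 1 and log2 of dose plus 1 gave 9. Leaving out the 50 µM array gave 28 and the 100 µM array 7, and these 7 did not include LOC101929305. Calls numbered 0 with dose in µM (260 genes at an unadjusted p under 0.05), any dose against vehicle (1367), no intensity trend (324) and the 10 µM array left out (949). The smallest adjusted p over these 4 fits ranged from 0.064 to 0.729. The cause of these shifts in the slope count was not tested.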

Other observations

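The tests of strict dose order in the cAMP list, of scaling and RNA shortening at 10 µM, of dose order in the interferon list and of other array orders, and the alternatives for the cAMP list's dose order, were chosen only after the result was seen.

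Between the arrays at 50 and 100 µM, which differed least, 7 of 27 lists stood apart, with 1.35 expected for lists of unrelated genes. Relative to 50 µM, heat shock and chaperone genes had a median of 0.13 log2 at 100 µM (99.7 percentile of matched random lists), cold response genes 0.14 (99.3 percentile), unfolded protein and integrated stress response genes 0.08 (99.5 percentile, with a mean of 0.02 and 0 of 29 past 1.5-fold) and immediate early genes 0.07 (99.6 percentile). NF-kappaB and inflammatory targets had a median of -0.17 (0.26 percentile), and the interferon list also lay low. Other stress lists did not stand apart, with NRF2 targets at the 31.8 percentile and p53 targets at the 76.2 percentile.

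Relative to 10 µM, erythroid and myeloid markers lay higher at 50 and 100 µM, with at most 1 gene of each list past 1.5-fold. The median of erythroid markers was 0.21 log2 at 50 µM (98.6 percentile) and 0.19 at 100 µM (99.0 percentile), and that of myeloid markers 0.25 (99.9 percentile) and 0.24 (99.95 percentile). The megakaryocyte, mast cell, B cell, T and NK cell and dendritic lists lay within the random range in both pairs. Cell cycle genes had a median of -0.18 at 100 relative to 10 µM (1.84 percentile).

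The cAMP list lay above vehicle at 50 and 100 µM. An unusual vehicle array as the whole cause is argued against by the treated arrays alone, where 100 minus 10 µM put the list at percentile 100 of matched random lists. After cyclic loess the list at 100 µM was again at percentile 100, but this could not decide on intensity-dependent bias. The random lists were matched on mean signal, so such a bias would move them together with the list. A shift common to genes of like signal therefore cannot by itself place the list above them. Of 31 members, 9 were strictly ordered by dose, and 7 of 24 without cross-hybridizing probe sets, where SIK1 and NR4A1 were not among them; both counts lay above all matched lists. This restates the order of the list's medians and is no separate evidence. A graded response to dmPGE2 remains a hypothesis, and it cannot be told apart from differences between arrays, since each dose had 1 array.

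The 10 µM array had 2.98 times as many genes past 1.5-fold as the 100 µM array. Array scaling is argued against, since the ratio was at least 2.61 under both other scalings. More shortening of RNA from the 5-prime end at 10 µM than on the other arrays is argued against by the control transcripts. The ACTB gap of 3.88 at 10 µM lay below those of the other 3 arrays, as did that of GAPDH. Both controls thus put the 10 µM array at the low extreme, so a difference in RNA quality the other way was not excluded. A bias by base composition remains a candidate explanation: genes of GC-rich chromosome 19 had a median of -0.10 log2 at 10 µM relative to the mean of 50 and 100 µM, below all random lists, and 100 of 921 (10.9%) were past 1.5-fold lower than vehicle. AT-rich chromosomes 4 (0.11, percentile 100) and 13 (0.11, percentile 99.99) went the other way. Chromosome 18 (0.06, 88.2 percentile) lay on the same side as these but did not reach the predicted bound. Chromosomes 22 (-0.08, percentile 0), 16 (-0.04, percentile 0.01), 17 (-0.03, percentile 0) and 11 (-0.02, percentile 0.47) also lay low. Chromosomes 2, 3, 5, 6, 8, 10 and 12 lay high, at percentiles from 98.23 to 100. The shift was thus not confined to chromosomes 4, 13 and 19. Chromosome membership alone cannot tell such a bias apart from an effect of 10 µM dmPGE2. Base composition itself was not measured.

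Interferon response genes lay higher at 50 µM than on the other arrays. After cyclic loess, 50 minus 100 µM was at percentile 100, but this could not decide on scaling. The random lists were matched on mean signal and would move together with the interferon list. The median at 100 relative to 50 µM (-0.27) is not the order that a dose-ordered response would give, but it restates the pattern and is no separate evidence. RNA from another blood cell type stays open: none of 6 marker lists passed the bound set beforehand, but that bound could not exclude it, since the T and NK list lay in the predicted direction (91.0 percentile for 50 minus 100 µM), with GNLY and CD247 highest at 50 µM. A response limited to 50 µM also stays open and was not tested.

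The order of dose gave 155 genes, and 7 of the 12 orders of the 4 arrays gave at least as many, up to 758. With 12 orders no share under 0.05 can be had. The order with 758 genes puts the 10 µM array at the far end from vehicle, as either a property of that array or a response largest at 10 µM would.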
